A study of Homo sapiens with 24 samples.

How the data were processed

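RNA from HCT-116 cells with p53 status p53+/+ or p53-/- was sequenced after 16 h without serum. The 24 libraries fall into 6 groups of 4 (2 lines by 3 kinds of RNA, cytosolic input, linear gradient polysomes and optimized gradient polysomes). Per the series design, cytosolic lysates were made from 6 plates of each line and shared out between the gradients. mRNA carrying more than 3 ribosomes was taken from the linear gradient and the peaks named 0 and +1 from the optimized one. The experiment was carried out 4 times. Per the labels' protocols, RNA was isolated with Tri-reagent and cleaned on columns, and libraries were made by Smart-seq2 from 10 ng of RNA or less and sequenced as a pool. Smart-seq2 amplifies polyadenylated RNA by PCR without molecular identifiers. Reads are therefore not independent molecules, and an interval from the counts of 1 library would cover counting error only. The intervals given here come from the spread among replicate libraries. Per the submitters' processing notes, reads were processed with Bowtie, for which no version is given, against the human genome build hg38. The program that counted reads, its treatment of multiply mapping reads, strand settings and any filtering are not given in the sources used here.

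The deposited values are whole read counts per gene and library, not normalized, as the authors' table gives them. The table held 19814 entries, of which 1539 merged several overlapping genes and carried 15.3% of all counts. Another 771 symbols appeared on more than 1 entry, making 2584 entries with 0.178% of the counts, and these were marked with a number sign and treated as uncertain. Every count column was matched to its sample by name, and 0 columns were without a sample. Gene coordinates, coding length and GC content were taken from GENCODE v29 on GRCh38 through the RefSeq accessions in the table. Of the tested entries, 10437 (90.8%) had a coding length and a GC content. Merged entries had no coordinates.

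Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Library sizes were scaled by TMM. Entries with low counts were removed by edgeR's filterByExpr, which left 11492 tested entries (918 of them merged). Quasi-likelihood models with a mean for each of the 6 groups were fitted to all 24 libraries, so that the groups share an estimate of spread. The common biological coefficient of variation was 0.489. Contrasts gave p53+/+ minus p53-/- in each kind of RNA, optimized minus linear polysomes for the mean of both lines and for each line. Others gave polysomal minus cytosolic RNA for each gradient as a mean of both lines. The remaining ones gave the interaction of p53 status with polysomal against cytosolic RNA for each gradient, and the difference of the p53 effects between gradients. Each used the Benjamini-Hochberg adjustment with a threshold of 0.05. Python 3.11.15 and matplotlib 3.10.9 were used for annotation and plots.

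These designs, the gene lists, the rule for named genes and all settings not called added were fixed before the data were examined. Named genes were, for each comparison, up to 10 with the largest positive and 10 with the largest negative log2 change among those past the threshold with a mean log2 CPM of at least 3 and no overlap between the libraries compared (within each line for means of both lines). TP53, CDKN1A and MDM2 were added in p53 comparisons, and up to 4 members of each gene list with the smallest p. Genes outside this rule are given where a count of a list needed examples.

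The 23 gene lists were p53 targets, G2 and M phase genes, G1/S and replication genes, ribosomal proteins, other TOP mRNAs (mRNAs with a 5' terminal oligopyrimidine tract), snoRNA host transcripts, nuclear long noncoding RNAs, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation genes, ATF4 targets, mRNAs with inhibitory upstream reading frames, mRNAs of the endoplasmic reticulum and secretory route, immediate early genes, cholesterol synthesis, glycolysis and hypoxia, interferon response, histones, short coding regions, long coding regions, and markers of colon epithelium, of MCF-7, of fibroblasts and of leukocytes. MCF-7 is a breast cancer line named in the growth protocol without a sample. The leukocyte list also held the globin genes HBA1 and HBA2. The table held 0 tested members of the nuclear noncoding and mitochondrial lists and 1 of the snoRNA hosts, which left 20 lists with at least 5 tested members. Merged entries were left out of lists. Lists were tested by camera with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. Camera asks whether genes of a list rank apart from all others. It was also run with an estimated correlation, beside fry, which asks whether the genes of a list move one way without comparing them with other genes.

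Replicate numbers were taken to pair the libraries because the series design states that the whole experiment was carried out 4 times and that lysates were divided. As a check, deviations from group means were correlated between libraries of equal number, with means of 0.166 to 0.504 over 9 pairs of groups. Correlations between different numbers are set by the centring and were not used. Single values under 0.1 were found for number 3 between linear libraries of the lines (-0.0212), between linear and cytosolic libraries of p53-/- cells (-0.0854) and between optimized and cytosolic ones (-0.174). Others were found for number 2 between linear and cytosolic libraries of p53+/+ cells (0.0896) and for number 1 between optimized and cytosolic libraries of p53-/- cells (0.0967). The model without a block had been chosen as the main one beforehand, and a replicate block was an alternative.

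The settings varied were RLE and upper quartile scaling, no low-count filter, a stricter filter (at least 5 CPM in 4 libraries), a replicate block, a block for each lysate, models of only the groups compared, DESeq2 1.42.0 Wald tests, limma-voom and a bound of 1 log2 unit on the change. Each library and each replicate number was left out in turn. For polysomal against cytosolic effects of p53, an analysis of partial variance was run with limma. Added after seeing the data were counts thinned to the smallest library total, the replicate block with a GC or a coding length correction, merged entries in lists, and the block with an estimated correlation. Equality of the gradients was described by the share of entries whose 95% confidence interval of the difference lay within 1 log2 unit. Effects that share cytosolic libraries were set against 20 simulations of unchanged groups, with libraries drawn independently rather than by lysate, and against a split of those libraries.

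Between replicates, log2 CPM correlated at 0.898 to 0.975, and the chi-square of counts per degree of freedom was 31.0 to 591, far above counting error. The procedures were tested on simulated counts with known changes in 11492 entries. The changed entries, 100 for each fold, were drawn from those with a mean log2 CPM of at least 3. The test of the lines in cytosolic RNA recovered 4% of 2-fold and 73% of 4-fold changes. That of optimized against linear polysomes recovered 37% and 95%, and the interaction of p53 status with linear polysomal against cytosolic RNA 1% and 23%.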

Results

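The deposited table held read counts from 24 libraries of HCT-116, a human colorectal carcinoma cell line, grown either with intact p53 (p53+/+) or from a derivative in which both TP53 alleles were disrupted (p53-/-). p53 is a transcription factor that switches on growth arrest, DNA repair and cell death genes. All cells had been starved of serum for 16 h. From each lysate, 3 kinds of RNA were sequenced, namely cytosolic input RNA, polysomal RNA from a linear sucrose gradient and polysomal RNA from an optimized non-linear gradient. Polysomal RNA is mRNA carrying several ribosomes, here more than 3 in the linear gradient. The 6 groups of line and RNA held 4 libraries each, since the experiment had been carried out 4 times. Library totals, in units of 1e6 counts, ranged from 11.6 to 16.4 in cytosolic RNA of p53+/+ cells, from 17.3 to 23.3 in cytosolic RNA of p53-/- cells, and from 16.9 to 32.2 in the polysomal libraries. The p-values measured the spread among these samples, and the labels did not say how far each repeat was an independent culture. Levels are TMM-scaled CPM (counts scaled to 1e6 per library), given as mean ± SD over 4 libraries, and effects are log2 fold changes with their standard errors (SE).

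**Figure D1:**
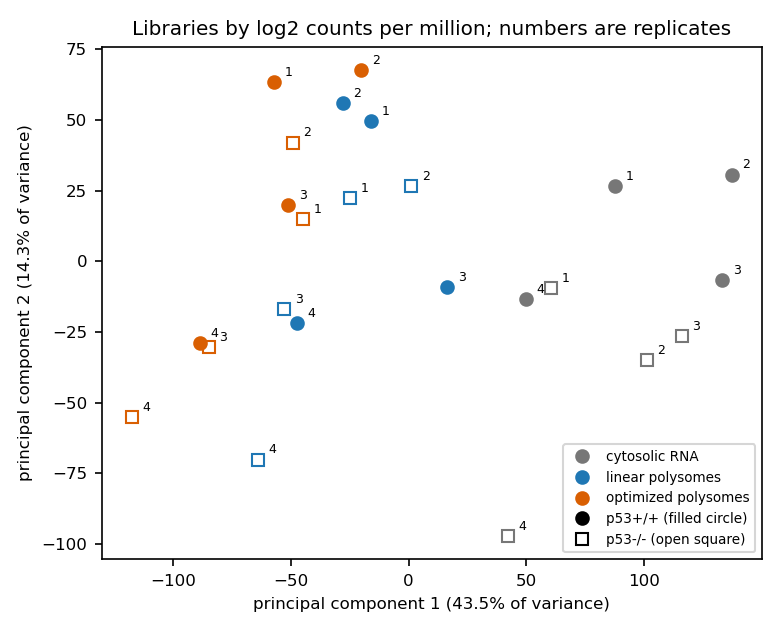
The plot places each of the 24 libraries by the first and second principal components of log2 CPM, with colour for the kind of RNA, filled circles for p53+/+, open squares for p53-/- and the replicate number beside each point. The first component held 43.5% of the variance and the second 14.3%.

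The targeted gene was examined first in every sample. TP53 (GRCh38, chromosome 17, 7661779 to 7687550, minus strand) overlaps the 5' end of WRAP53 (chromosome 17, 7686071 to 7703502, plus strand), and the deposited table merged both protein-coding genes into a single entry, TP53+WRAP53. That entry was higher in p53+/+ cells in all 3 kinds of RNA, at 368 ± 92.7 against 148 ± 38.9 CPM in cytosolic RNA, 333 ± 108 against 109 ± 25.9 CPM in linear polysomes and 388 ± 161 against 139 ± 44.5 CPM in optimized polysomes. The log2 differences for TP53+WRAP53 were 1.31, 1.61 and 1.48, with adjusted p = 0.0457, 0.0127 and 0.0240 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Single libraries ranged from 75.8 to 201 CPM in p53-/- cells and from 181 to 546 CPM in p53+/+ cells. As the table gives 1 count for both genes, their reads could not be told apart here, and a disrupted TP53 gene may still leave transcript. The remaining counts in p53-/- cells were therefore no sign of a wrong label. The cytosolic call of this entry was lost without a low-count filter, with limma-voom and when a whole replicate number was left out, and the optimized one when only the groups compared were fitted.

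**Figure D2:**
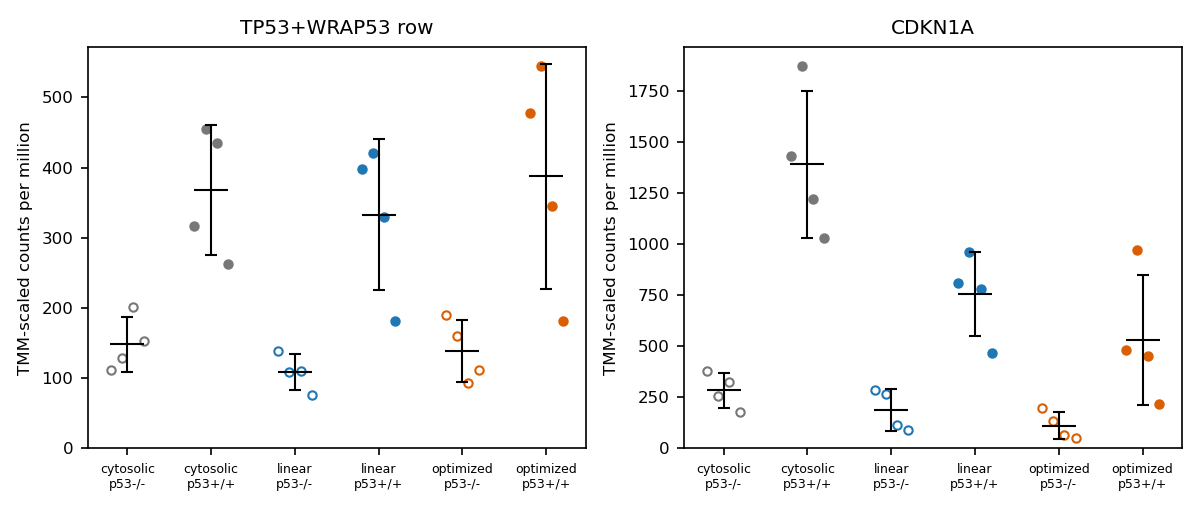
TMM-scaled CPM of the TP53+WRAP53 entry (left) and of CDKN1A (right) are plotted for each library in the 6 groups, with open points for p53-/-, filled points for p53+/+, and the black bars giving mean ± SD of 4 libraries. CDKN1A averaged 285 CPM in cytosolic RNA of p53-/- cells and 1391 CPM in that of p53+/+ cells.

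The first comparison asked how the lines differed in cytosolic mRNA. CDKN1A (GRCh38, chromosome 6, 36676460 to 36687339), which encodes the cell cycle inhibitor p21 and is a classic p53 target, was 4.88-fold higher in p53+/+ cells at 1391 ± 363 against 285 ± 86.2 CPM. EHF (chromosome 11, 34621093 to 34661057), an epithelial transcription factor of the ETS family, reached 10.4 ± 5.29 CPM in p53+/+ cells and 0.0694 ± 0.0933 CPM in p53-/- cells. CASP4, an inflammatory caspase, SULT1A1, a sulfotransferase, and S100A4, a calcium-binding protein linked to cell motility, were also higher in p53+/+ cells. In the other direction, ZBED2, a zinc finger protein, fell from 46.1 ± 18.7 CPM in p53-/- to 1.67 ± 1.11 CPM in p53+/+ cells, and MIA, a small secreted protein, from 39.0 ± 7.80 to 2.67 ± 0.690 CPM. In total, 106 entries were higher and 71 lower among 11492 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1474 had an unadjusted p under 0.05. The median size of a called change was 2.64 log2 units.

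By that test, CDKN1A changed by 2.29 log2 units (SE 0.46) with adjusted p = 0.00694, EHF by 7.10 (SE 0.80) with adjusted p = 4.62e-06 and CASP4 by 5.75 (SE 0.57) with adjusted p = 1.5e-06. Other genes far higher in p53+/+ cells were TNFRSF10C (4.72), a decoy receptor for the death ligand TRAIL, the merged entry ARAF+SYN1 (3.74), MPP7 (3.48), ACTA2 (3.02), the smooth muscle actin, RGS2 (2.92), a regulator of G protein signalling, SULT1A1 (2.85) and S100A4 (2.38). Of the genes named by rule, TM4SF18 (-8.44), a tetraspan membrane protein, ZBED2 (-4.73), MIA (-3.88), PLK2 (-2.87), a polo-like kinase, and WNT16 (-2.65), a secreted Wnt ligand, had the lowest values. Next were ECM1 (-2.64), CHAC1 (-2.40), a glutathione-degrading enzyme, ARL4A (-2.35), CAMK2D (-2.33) and PKIB (-2.30). For each of these genes, CDKN1A included, every library of a line lay above every library of the other. MDM2, the ubiquitin ligase that is itself a p53 target, had a log2 value of 0.67 with adjusted p = 0.453 by edgeR's quasi-likelihood test. With the replicate number as a block, 830 entries were called. Leaving out a whole replicate number ended the calls of 10 of the 21 genes named by rule, CDKN1A among them, and limma-voom those of ACTA2, RGS2, ARL4A and PKIB, while fitting the cytosolic libraries alone ended those of PKIB and PLK2.

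Among the gene lists, 2 of the 80 tested p53 targets were higher in cytosolic RNA of p53+/+ cells, CDKN1A and GDF15 (1.62, a secreted stress cytokine), PLK2 was lower and 77 did not pass, against 3 and 1 when adjusted over the list alone. The list as a whole lay higher, with a median of 0.37 and adjusted p = 1.54e-04 by camera with Benjamini-Hochberg adjustment over the lists, and adjusted p = 0.130 with an estimated correlation. PHLDA3, a p53 target that restrains Akt, had a value of 1.27 with adjusted p = 0.0642 by edgeR's quasi-likelihood test, and 0.00442 with the replicate block. Of 22 cholesterol synthesis genes, FDFT1 (-1.04), the squalene synthase, was lower and 21 did not pass, against 4 lower when adjusted over the list alone. The median of that list was -0.73, with a camera adjusted p = 9.02e-05, and adjusted p = 0.0653 with an estimated correlation. Of 32 interferon response genes, BST2 (1.86), which tethers budding viruses, and IFI35 (1.17) were higher and 30 did not pass, against 4 higher when adjusted over the list alone (median 0.36, camera adjusted p = 8.34e-04, and adjusted p = 0.0653 with an estimated correlation). Among 67 mRNAs with very long coding regions, GCN1 (1.34) and LAMA5 (1.97) were higher and 65 did not pass, with a median of 0.45 (camera adjusted p = 1.70e-05, and adjusted p = 0.486 with an estimated correlation). Under the replicate block, 13 p53 targets were higher and 2 lower, 8 cholesterol synthesis genes were lower, and 5 interferon response genes and 6 long coding region mRNAs were higher. RLE scaling ended the calls of FDFT1 and IFI35 (adjusted p = 0.0793 and 0.0577 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), as did leaving out the low-count filter (0.0517 and 0.0624), and upper quartile scaling ended that of FDFT1 (0.0848). Of the 17 list members called in cytosolic RNA, leaving out some library ended the calls of 9 and leaving out some replicate number those of 15.

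The ATF4 target list, genes of the amino acid stress response, held 1 lower member of 33 in cytosolic RNA, CHAC1, and 4 lower when adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.00638, and adjusted p = 0.351 with an estimated correlation). Lower camera calls without any single member past the threshold were made for nuclear oxidative phosphorylation genes (64 tested, median -0.35, adjusted p = 0.00727), G2 and M phase genes (48 tested, median -0.37, adjusted p = 0.0345), G1/S and replication genes (45 tested, median -0.30, adjusted p = 0.0354) and histones (32 tested, median -0.48, adjusted p = 0.0354). Each of these had adjusted p = 0.812 with an estimated correlation. Short coding region mRNAs had a median of -0.44 (camera adjusted p = 0.0141, and adjusted p = 0.840 with an estimated correlation), with S100A4 higher and S100A10 (-1.57) lower among 47. Of the fibroblast markers, ACTA2 was higher among 7 tested (median 0.82, camera adjusted p = 0.0354, and adjusted p = 0.356 with an estimated correlation). The endoplasmic reticulum and secretory list held MET (1.70), the receptor for hepatocyte growth factor, LAMA5 and LAMB1 (1.67) higher and TACSTD2 (-10.0) lower among 74. Its camera adjusted p = 0.0643, and 0.0356 with the replicate block, where adjusted p = 0.733 with an estimated correlation. Camera adjusted p values of the lists not past the threshold were 0.208 for ribosomal proteins, 0.535 for other TOP mRNAs, 0.886 for mRNAs with inhibitory upstream reading frames, 0.931 for immediate early genes, 0.0983 for glycolysis and hypoxia, 0.931 for epithelial markers, 0.886 for MCF-7 markers and 0.359 for leukocyte markers. In these lists CA12 (3.87, adjusted p = 0.0398 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), both an MCF-7 marker and a hypoxia gene, was higher and SLC2A3 (-2.48, adjusted p = 0.0419), a glucose transporter, lower. The stricter filter removed CA12, and RLE scaling ended the call of SLC2A3. The block called 6 ATF4 targets, 5 G1/S genes and 3 G2 and M phase genes lower, while 7 secretory genes were higher and 5 lower, glycolysis genes held 1 higher and 3 lower, and upstream reading frame mRNAs 1 and 1.

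The same question was asked of RNA on polysomes from the linear gradient. EHF rose to 25.8 ± 5.33 CPM in p53+/+ cells against 0.0596 ± 0.0745 CPM in p53-/- cells, and SULT1A1 to 38.5 ± 7.33 against 2.49 ± 0.798 CPM. CDKN1A was 4.00-fold higher, at 755 ± 207 against 189 ± 103 CPM. ZBED2 was lower and averaged 142 ± 35.3 CPM in p53-/- cells, as was WNT16, which averaged 20.9 ± 5.78 CPM in p53+/+ cells and 202 CPM in p53-/- cells. In linear polysomes, 80 entries were higher and 30 lower in p53+/+ cells among 11492 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 796 had an unadjusted p under 0.05.

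By the same test the log2 values were 8.71 for EHF (SE 0.79, adjusted p = 2.64e-07), 3.94 for SULT1A1 (SE 0.36, adjusted p = 2.64e-07), 2.00 for CDKN1A (SE 0.46, adjusted p = 0.0243) and -4.83 for ZBED2 (SE 0.48, adjusted p = 6.98e-07). TNFRSF10C (6.73), ARAF+SYN1 (4.72), CASP4 (4.51), S100A4 (3.54), RGS2 (3.32), BST2 (2.40), MPP7 (2.31) and ADGRF1 (2.27), an adhesion G protein-coupled receptor, were also higher. TM4SF18 (-5.71), WNT16 (-3.27), MIA (-3.26), CHAC1 (-2.28), ARL4A (-2.20), PTP4A1 (-1.93), a phosphatase, ECM1 (-1.90), NECTIN3 (-1.79), a cell adhesion protein, and CAMK2D (-1.73) were lower. MDM2 had a value of 0.35 with adjusted p = 0.987 by edgeR's quasi-likelihood test. The replicate block gave 295 calls, while 67 were left without replicate 1 of the p53-/- linear libraries and 72 without replicate 4 of them. Leaving out a whole replicate number ended the calls of 10 of the 22 genes named by rule, CDKN1A, BST2 and ADGRF1 among them, and thinning the counts to the smallest library total ended those of ECM1, MPP7 and CAMK2D. The median of all tested entries moved from -0.04 with TMM to 0.06 with upper quartile scaling.

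Of the 80 p53 targets, 4 were higher in linear polysomes and none lower, against 5 and 1 when adjusted over the list alone. They were CDKN1A, GDF15 (1.77), PHLDA3 (1.64) and DDB2 (1.22), a DNA damage recognition protein, and the list had a median of 0.22 with a camera adjusted p = 8.43e-05, and adjusted p = 0.0983 with an estimated correlation. Interferon response genes had the highest list median, 0.75, with BST2, HERC5 (1.73) and IFI35 higher of 32 and 7 higher when adjusted over the list alone (camera adjusted p = 2.58e-10, and adjusted p = 0.000845 with an estimated correlation). The 22 cholesterol synthesis genes had a median of -0.81 with no single call, against 3 lower when adjusted over the list alone (camera adjusted p = 5.85e-08, and adjusted p = 0.00867 with an estimated correlation). IDI1, an isomerase of that pathway, had a value of -1.41 with adjusted p = 0.350 by edgeR's quasi-likelihood test, and 0.00197 with the replicate block. ATF4 targets lay lower with CHAC1 as the single call (median -0.40, camera adjusted p = 2.64e-05, and adjusted p = 0.0851 with an estimated correlation). ATF4 itself, the transcription factor whose mRNA carries inhibitory upstream reading frames, had a value of -1.10 with adjusted p = 0.0495 by edgeR's quasi-likelihood test. That call ended with RLE scaling (adjusted p = 0.0870), with upper quartile scaling (0.106) and without the low-count filter (0.0813), and the call of HERC5 ended without the filter (0.0753). Of the 16 list members called in linear polysomes, leaving out some library ended the calls of 11 and leaving out some replicate number those of 13.

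Long coding region mRNAs lay higher in linear polysomes of p53+/+ cells with GCN1 (1.52) and LAMA5 (2.15) called (median 0.56, camera adjusted p = 3.08e-10, and adjusted p = 0.224 with an estimated correlation). G1/S genes (median -0.31, camera adjusted p = 0.00142) and G2 and M phase genes (median -0.21, camera adjusted p = 0.0376) lay lower without a single call, and had adjusted p = 0.395 and 0.658 with an estimated correlation. The secretory list, with MET (1.71) and LAMA5 higher and TACSTD2 (-5.16), an epithelial surface antigen, lower, had a median of 0.15 (camera adjusted p = 0.0376, and adjusted p = 0.551 with an estimated correlation). Other TOP mRNAs, glycolysis genes and fibroblast markers passed only with the replicate block, where camera gave adjusted p = 0.0459, 0.0243 and 0.0134 in place of 0.0840, 0.0573 and 0.0672. Of these markers, ACTA2 (2.24) was called higher without the block too. With the block and an estimated correlation these had adjusted p = 0.366, 0.361 and 0.149. The other lists did not pass, with camera adjusted p values of 0.990 for ribosomal proteins, 0.384 for oxidative phosphorylation, 0.151 for upstream reading frame mRNAs, 0.294 for immediate early genes, 0.882 for histones, 0.636 for short coding regions (S100A4 called higher, S100A10 lower), 0.800 for epithelial, 0.294 for MCF-7 and 0.133 for leukocyte markers. Fitted with the block, 9 p53 targets were higher and 1 lower, 6 interferon response genes, 4 secretory genes and 2 fibroblast markers were higher, and 6 cholesterol synthesis genes, 4 ATF4 targets, 1 G1/S gene and 1 glycolysis gene were lower. Upstream reading frame mRNAs then held 1 higher and 2 lower.

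In polysomes from the optimized gradient, EHF averaged 36.4 ± 12.8 CPM in p53+/+ and 0.0388 ± 0.0471 CPM in p53-/- cells, and SULT1A1 44.1 ± 8.99 against 2.24 ± 0.479 CPM. HDAC2, a histone deacetylase, was 6.59-fold higher in p53+/+ cells at a mean of 137 CPM against 20.8 ± 3.83 CPM. CDKN1A was 4.76-fold higher, at 532 ± 318 against 112 ± 67.3 CPM. ZBED2 averaged 4.90 ± 1.55 CPM in p53+/+ and 120 ± 11.8 CPM in p53-/- cells. There were 90 higher and 19 lower entries among 11492 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 790 had an unadjusted p under 0.05. In that test EHF had a log2 value of 9.73 (SE 0.82, adjusted p = 5.68e-08), SULT1A1 4.30 (SE 0.37, adjusted p = 5.68e-08), HDAC2 2.72 (SE 0.37, adjusted p = 5.38e-05) and CDKN1A 2.25 (SE 0.46, adjusted p = 0.00945). TNFRSF10C (6.16), ARAF+SYN1 (4.46), CASP4 (3.88), RGS2 (3.37), S100A4 (3.19), GFY (2.81) and MPP7 (2.41) were also higher. TM4SF18 (-6.19), ZBED2 (-4.62), WNT16 (-3.44), MIA (-3.29), ARL4A (-2.32), CHAC1 (-2.30), ICE2 (-2.21), NECTIN3 (-2.10), CAMK2D (-1.70) and FUT8 (-1.63), a fucosyltransferase, were lower. MDM2 had a value of 0.87 with adjusted p = 0.543 by edgeR's quasi-likelihood test. The replicate block gave 349 calls, while 63 were left without replicate 4 and 66 without replicate 3 of the p53-/- optimized libraries. Leaving out a whole replicate number ended the calls of 8 of the 22 genes named by rule, CDKN1A among them, and fitting only the groups compared also ended that of CDKN1A.

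The p53 targets called in optimized polysomes were CDKN1A, GDF15 (1.78), PHLDA3 (1.61) and DDB2 (1.37), that is 4 higher and none lower of 80, against 5 and 1 when adjusted over the list alone (median 0.36, camera adjusted p = 2.38e-06, and adjusted p = 0.0441 with an estimated correlation). Interferon response genes lay higher with BST2 (1.80) and IFI35 (1.38) called and 5 when adjusted over the list alone (median 0.49, camera adjusted p = 2.38e-06, and adjusted p = 0.00579 with an estimated correlation). Cholesterol synthesis genes lay lower with no single call and 7 when adjusted over the list alone (median -0.71, camera adjusted p = 1.51e-08, and adjusted p = 0.00579 with an estimated correlation). HMGCS1 had a value of -1.69 with adjusted p = 0.237 by edgeR's quasi-likelihood test, and 3.62e-05 with the replicate block. CHAC1 and CLIC4 (-1.16) were the called ATF4 targets (median -0.41, camera adjusted p = 3.85e-05, and adjusted p = 0.0799 with an estimated correlation). ATF4 itself had -0.87 with adjusted p = 0.191 by edgeR's quasi-likelihood test, and 0.0316 with the replicate block. Long coding region mRNAs lay higher with GCN1 and LAMA5 (2.16) called (median 0.31, camera adjusted p = 3.03e-05, and adjusted p = 0.431 with an estimated correlation). Of the secretory list, LAMA5 and MET (1.42) were higher with a camera adjusted p = 0.138 for the list. RLE scaling ended the call of BST2 (adjusted p = 0.0536 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the 13 list members called in optimized polysomes, leaving out some library ended the calls of 9 and leaving out some replicate number those of 11.

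Without a call of any single member, G2 and M phase genes (median -0.33, camera adjusted p = 0.00358), G1/S genes (median -0.28, adjusted p = 0.00388), ribosomal proteins (median -0.11, adjusted p = 0.0125), other TOP mRNAs (median -0.24, adjusted p = 0.0112) and glycolysis genes (median -0.27, adjusted p = 0.0439) lay lower in optimized polysomes of p53+/+ cells. With an estimated correlation these had adjusted p = 0.521, 0.466, 0.776, 0.431 and 0.294. Fibroblast markers, with ACTA2 (2.34) called, lay higher (median 0.63, camera adjusted p = 0.0488, and adjusted p = 0.294 with an estimated correlation). Camera adjusted p values of the rest were 0.544 for oxidative phosphorylation, 0.436 for upstream reading frame mRNAs, 0.755 for immediate early genes, 0.402 for histones, 0.577 for short coding regions, 0.689 for epithelial, 0.364 for MCF-7 and 0.0523 for leukocyte markers. Once replicates were blocked, 12 p53 targets were higher and 1 lower, 5 interferon response genes and 2 fibroblast markers were higher, and 8 cholesterol synthesis genes, 4 ATF4 targets and 1 glycolysis gene were lower. Secretory genes then held 4 higher and 3 lower, upstream reading frame mRNAs 1 and 2, and short coding region mRNAs 1 and 1.

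The series set an optimized gradient beside a linear one, so the p53 effects measured with both were compared gene by gene. Of the called genes, 66 were higher and 13 lower in both gradients, with none in opposite directions, where independent lists of these sizes would share 0.627 and 0.0496. Another 31 entries passed in linear and 30 in optimized polysomes alone. Across the 11492 entries, which are not independent replicates, Pearson's r between the effects was 0.697 and Spearman's rho 0.662. The gradients shared lysates but no libraries. By edgeR's quasi-likelihood test of the difference between the p53 effects of the gradients, 0 entries passed (57 at an unadjusted p under 0.05, smallest adjusted p = 0.605), against 1 with DESeq2 and 0 with limma-voom. EHF, SULT1A1, CASP4, TNFRSF10C, S100A4, RGS2, ZBED2, WNT16, MIA, TM4SF18 and CHAC1 were among the 66 genes called in cytosolic RNA and with both gradients, of which 53 were higher and 13 lower in p53+/+ cells. Of these 66 genes, 2 belonged to the p53 target list, and of the 228 genes called in at least 1 kind of RNA, 5 did. That list held 80 of the 11492 tested entries.

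**Figure D3:**
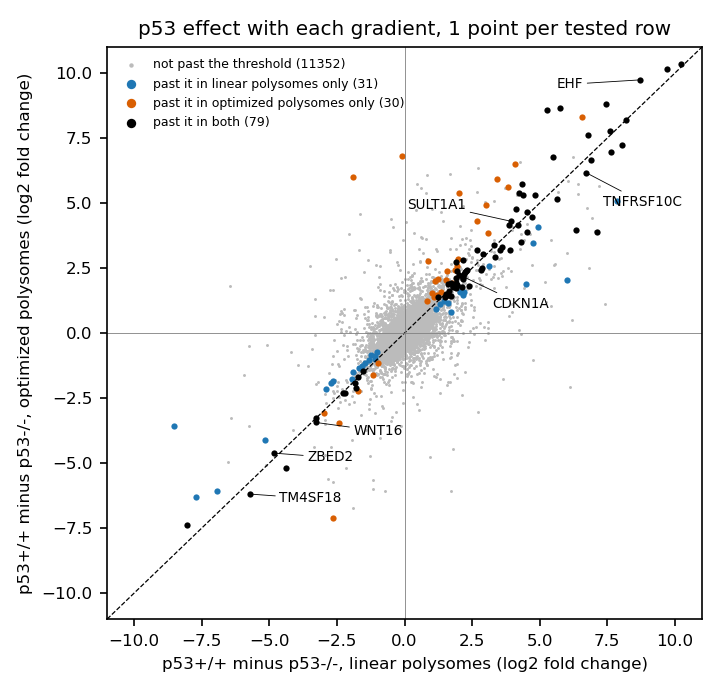
Each point is a tested entry, with its log2 fold change between p53+/+ and p53-/- cells in linear polysomes on the horizontal axis and in optimized polysomes on the vertical axis. Colour gives whether its adjusted p was under 0.05 in either, and the dashed line marks equal values. The 79 entries past the threshold in both lay in the upper right and lower left quadrants.

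The spread among replicates was estimated for each group. The biological coefficient of variation estimated by edgeR was 0.454 and 0.454 in linear polysomes of p53+/+ and p53-/- cells and 0.462 and 0.477 in optimized polysomes, against 0.536 and 0.560 in cytosolic RNA. With counts thinned to the smallest library total, it was 0.442 and 0.449 in linear and 0.455 and 0.471 in optimized polysomes.

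Polysomal RNA from the optimized gradient was then compared with that from the linear gradient, averaged over both lines. ATP6V1A (GRCh38, chromosome 3, 113747019 to 113812056), a subunit of the vacuolar proton pump, rose from 11.7 ± 1.84 to 28.9 ± 6.92 CPM in p53-/- cells and from 11.6 ± 2.83 to 28.5 ± 6.24 CPM in p53+/+ cells. LTA4H, an enzyme of leukotriene synthesis, and CTNNB1, the adhesion and Wnt pathway protein beta-catenin, were higher with the optimized gradient as well. ATP5D, a subunit of ATP synthase, fell from 539 ± 80.4 to 262 ± 94.7 CPM in p53-/- cells and from 704 ± 220 to 314 ± 83.3 CPM in p53+/+ cells. PTMS, a small acidic nuclear protein, fell from 100 ± 26.9 to 45.6 ± 8.35 CPM and from 129 ± 21.6 to 60.0 ± 13.8 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 78 entries were higher and 277 lower among 11492, and 2576 had an unadjusted p under 0.05. The median size of a called change was 0.90 log2 units, smaller than in the comparisons of the lines.

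In that test ATP6V1A changed by 1.30 log2 units (SE 0.27), LTA4H by 1.23 (SE 0.23), ATP5D by -1.10 (SE 0.21) and PTMS by -1.12 (SE 0.19), each with adjusted p = 0.0288. The merged entry CEP95+DDX5 (1.28), PLS3 (1.19), an actin-bundling protein, HSD17B4 (1.16), a peroxisomal enzyme, NT5C2 (1.11), PPP2R1B+SIK2 (1.03), TM9SF2 (1.01), CTNNB1 (0.96) and MED17 (0.94) were higher. C9orf69 (-1.22), MSX1 (-1.12), SF3B5 (-1.10), a splicing factor subunit, IMPA2 (-1.07), RFNG (-1.06), MPV17L2 (-1.05), TXN2 (-1.05), the mitochondrial thioredoxin, and PFN1 (-1.04), profilin, were lower. With the replicate block, 2688 entries were called, all 355 of the above among them, whereas RLE scaling left 12 calls (7 higher and 5 lower) and ended those of 14 of the 20 genes named by rule. The count was 0 without replicate 1 or replicate 3 of the p53+/+ optimized libraries, replicate 2 or replicate 4 of the p53-/- optimized ones, replicate 2 of the p53-/- linear ones or replicate 3 of the p53+/+ linear ones. It was 2 without replicate 3 of the p53-/- optimized ones, and 12 and 142 without replicate 4 and replicate 3 of the p53-/- linear ones. It was 34 without replicate 4 and 545 without replicate 2 of the p53+/+ linear ones.

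Several gene groups lay lower with the optimized gradient. Short coding region mRNAs lay lower with the optimized gradient in 47 of 47 members, of which 6 were called, among them PFN1, CHCHD2 (-1.01) and DYNLRB1 (-0.99), and 22 when adjusted over the list alone (median -0.61, camera adjusted p = 3.13e-10). Of 68 ribosomal protein mRNAs, 7 were lower and 61 did not pass, against 35 lower when adjusted over the list alone, with RPL32 (-0.97), RPS26 (-0.96) and RPL28 (-0.91) as examples (median -0.57, camera adjusted p = 2.78e-12). Of 64 oxidative phosphorylation genes, 14 were lower, such as NDUFS8 (-1.08) and COX6B1 (-1.07), 1 was higher, NDUFS1 (0.99), and 49 did not pass, against 31 lower and 5 higher when adjusted over the list alone (median -0.60, camera adjusted p = 2.46e-09). Of 32 histones, whose reads are uncertain because copies are nearly identical and the transcripts lack poly(A) tails, 5 were lower, with HIST1H2AM (-1.34) and HIST1H4E (-1.26) as examples, and 10 when adjusted over the list alone (median -1.03, camera adjusted p = 5.21e-10). With an estimated correlation these lists had adjusted p = 0.342 for short coding regions, 0.302 for ribosomal proteins, 0.342 for oxidative phosphorylation and 0.302 for histones. In the fit with the replicate block, 27 short coding region mRNAs, 39 ribosomal proteins and 18 histones were lower, and 40 oxidative phosphorylation genes were lower and 5 higher.

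Among lists that lay higher, G1/S genes had MCM3 (1.06) and MCM4 (0.81), parts of the replicative helicase, called of 45 (median 0.45, camera adjusted p = 5.74e-05), and 2 when adjusted over the list alone. G2 and M phase genes had a median of 0.56 (camera adjusted p = 3.21e-06), with KIF2C (0.76) higher but BIRC5 (-0.90), the apoptosis inhibitor survivin, and FOXM1 (-0.70) lower of 48, against 2 and 3 when adjusted over the list alone. The secretory list had HSPA5 (1.21) and CANX (0.80), chaperones of the endoplasmic reticulum, TFRC (0.98), the transferrin receptor, and SLC3A2 (0.67) higher of 74 (median 0.25, camera adjusted p = 4.22e-04), and 4 when adjusted over the list alone. Glycolysis genes had P4HA2 (0.74) and ENO1 (0.64) higher of 30, against 4 higher and 1 lower when adjusted over the list alone (median 0.32, camera adjusted p = 3.36e-04). Long coding region mRNAs (median 0.24, camera adjusted p = 5.03e-04), epithelial markers (8 tested, median 0.50, adjusted p = 0.00605), other TOP mRNAs (22 tested, median 0.22, adjusted p = 0.0315) and cholesterol synthesis genes (median 0.31, adjusted p = 0.0315) also lay higher. The single call in cholesterol synthesis, PMVK (-0.86), was lower. With an estimated correlation, adjusted p lay at 0.192 for glycolysis genes, at 0.366 for long coding regions and other TOP mRNAs, and at 0.302 for the others named as higher. ATF4 targets had CTH (0.90), AARS (0.86), ASNS (0.85) and SLC3A2 higher of 33, against 6 higher and 2 lower when adjusted over the list alone, and a camera adjusted p = 0.0552, which was 0.0411 with the replicate block. With the block and an estimated correlation it was adjusted p = 0.316. Camera adjusted p values were 0.805 for p53 targets, where RHOC (-0.80) was the single call, 0.166 for upstream reading frame mRNAs, 0.805 for immediate early genes, 0.440 for interferon response genes, where IFITM2 (-1.03) and ISG15 (-0.95) were lower, 0.805 for MCF-7, 0.440 for fibroblast and 0.0862 for leukocyte markers. By the blocked fit, 18 G1/S genes were higher and 1 lower, 21 and 3 G2 and M phase genes, 12 and 4 secretory genes, 12 and 1 glycolysis genes, 3 and 0 long coding region mRNAs, and 3 and 1 epithelial markers. Other TOP mRNAs then held 7 higher and 3 lower, cholesterol synthesis genes 7 and 2, ATF4 targets 10 and 4, p53 targets 5 and 12, and interferon response genes 2 and 5. Upstream reading frame mRNAs and immediate early genes held 1 and 3 each, MCF-7 markers 1 and 0, and leukocyte markers 0 and 2 (HBA1 and HBA2). Of the 51 list members called between the gradients, RLE scaling ended the calls of 50, upper quartile scaling those of 6 and leaving out the filter those of 39, and each of the 51 ended without some library.

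Within each line taken alone, edgeR's quasi-likelihood test called 0 entries between the gradients in p53+/+ cells (1077 at an unadjusted p under 0.05, smallest adjusted p = 0.442) and 0 in p53-/- cells (1203, and 0.450). In p53+/+ cells DESeq2 and limma-voom also called 0, and in p53-/- cells DESeq2 called 11 and limma-voom 0. With the replicate block, 10 entries were called in p53+/+ and 483 in p53-/- cells. Of the lists, 10 passed by camera in p53+/+ and 12 in p53-/- cells, such as ribosomal proteins with medians of -0.66 and -0.48 and histones with -1.07 and -0.98, and 0 passed in either line with an estimated correlation. ATF4 targets and cholesterol synthesis genes passed in p53+/+ cells with the replicate block alone, each with a camera adjusted p = 0.0352, and adjusted p = 0.308 and 0.447 with the block and an estimated correlation. A missed threshold does not show that the gradients gave equal values, and the 95% confidence interval of the difference averaged over both lines lay within 1 log2 unit of 0 for 4484 of 11492 entries, or 39.0%.

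Polysomal and cytosolic RNA were compared next, averaged over both lines, to show which mRNAs were loaded with ribosomes. FTL (GRCh38, chromosome 19, 48965301 to 48966878), the ferritin light chain whose translation is held back by iron regulatory proteins, fell from 18810 ± 6397 CPM in cytosolic RNA of p53-/- cells to 289 ± 58.6 CPM in their linear polysomes and 307 ± 20.6 CPM in their optimized polysomes. GPX4 (chromosome 19, 1103926 to 1106791), a selenoprotein that protects membrane lipids from oxidation, fell from 4868 ± 817 CPM to 85.0 ± 16.8 and 69.2 ± 13.1 CPM in the same cells. HMGB1 and HMGB2, abundant chromatin proteins, were 5.23- and 4.69-fold higher in linear polysomes than in cytosolic RNA, and LDHB, a subunit of lactate dehydrogenase, 6.99-fold higher in optimized polysomes. Of 11492 entries, 3260 were higher and 1907 lower in linear polysomes, and 4070 higher and 2789 lower in optimized polysomes, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 5998 and 7284. The median of all tested entries lay at 0.27 and 0.30 with TMM scaling but at 0.06 and 0.10 with RLE and 0.13 and 0.14 with upper quartile scaling, a shift of up to 0.20 and 0.19. The log2 values printed are those with TMM scaling, without that median taken off. RLE scaling gave 2449 higher and 2385 lower entries in linear and 3554 and 3208 in optimized polysomes.

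In linear polysomes that test gave log2 values of -5.69 for FTL (SE 0.24, adjusted p = 8.27e-15), -5.51 for GPX4 (SE 0.28, adjusted p = 2.11e-13) and 2.47 for AHCYL1, a regulator of calcium release (SE 0.25, adjusted p = 2.39e-08). C9orf16 (-5.34), SEPW1 (-5.23), another selenoprotein, GUK1 (-5.07), the guanylate kinase, NME4 (-4.61), C6orf1 (-4.54), the merged entry BEST1+FTH1 (-4.35), which holds the ferritin heavy chain, TMEM219 (-4.35) and CNFN (-4.31) were the next lowest. SUDS3 (2.54), BBX (2.45), HMGB1 (2.39), CTCF (2.34), GDAP1 (2.29), TTF1 (2.24), PICALM (2.24), NMI (2.24) and HMGB2 (2.23) were the highest besides AHCYL1. In optimized polysomes the values were -5.97 for GPX4 (SE 0.29, adjusted p = 5.07e-14), -5.65 for FTL (SE 0.24, adjusted p = 9.45e-15), 2.85 for PICALM (SE 0.32, adjusted p = 4.31e-08) and 2.81 for LDHB (SE 0.30, adjusted p = 2.26e-08). C9orf16 (-5.75), SEPW1 (-5.61), GUK1 (-5.22), C6orf1 (-5.13), NENF (-4.89), TMEM219 (-4.88), NME4 (-4.80) and CCDC57 (-4.80) were also among the lowest. GDAP1 (2.95), SHQ1 (2.94), LTV1 (2.92), KIN (2.87), BBX (2.83), EIF2B3 (2.81), UPF3B (2.79) and SLC27A2 (2.77) were among the highest. ATF4 was lower in both, at -1.98 and -2.36 (adjusted p = 2.34e-08 and 6.07e-10 by edgeR's quasi-likelihood test). All 20 named genes of each comparison kept their calls under every alternative setting tried.

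Of 68 ribosomal protein mRNAs, 45 were lower, 4 higher and 19 not past the threshold in linear polysomes, and in optimized polysomes 52, 4 and 12, with medians of -1.28 and -2.01. RPLP0 (-3.29 and -3.64), RPLP1 (-3.80 and -4.57) and RPS29 (-4.08 and -4.59) were examples, and camera gave adjusted p = 5.15e-25 and 4.83e-25, and adjusted p = 0.471 and 0.432 with an estimated correlation. Short coding region mRNAs held 31 lower and 2 higher of 47 in linear and 41 lower and 0 higher in optimized polysomes, such as MT2A (-2.37 and -3.01), a metallothionein, and S100A16 (-2.52 and -3.39). The medians were -1.38 and -2.14 (camera adjusted p = 2.65e-17 and 3.02e-18, and adjusted p = 0.661 and 0.583 with an estimated correlation). Adjusted over the list alone, 35 and 41 of them were lower. Oxidative phosphorylation genes held 32 lower and 15 higher of 64 in linear and 39 lower and 12 higher in optimized polysomes, with COX8A (-2.96 and -3.80) and UQCR11 (-3.54 and -3.97) as examples (medians -0.59 and -1.42, camera adjusted p = 9.41e-05 and 2.69e-07, and adjusted p = 0.942 and 0.615 with an estimated correlation). Histones held 14 and 25 lower and none higher of 32, for instance HIST1H3J (-1.92 and -3.06), with medians of -1.13 and -2.26 (camera adjusted p = 2.13e-04 and 3.64e-07, and adjusted p = 0.942 and 0.583 with an estimated correlation). After blocking by replicate, histones held 18 lower and 1 higher in linear polysomes, and short coding region mRNAs 41 lower and 1 higher in optimized ones. Less the median of all entries, the list medians were -1.54 and -2.31 for ribosomal proteins, -1.64 and -2.43 for short coding regions, -0.86 and -1.71 for oxidative phosphorylation and -1.40 and -2.55 for histones.

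Of 45 G1/S genes, 22 were higher and 3 lower in linear and 31 higher and 5 lower in optimized polysomes, for instance FEN1 (1.60 and 2.05), RAD51 (1.95 and 2.26) and RRM2 (1.29 and 1.65). Their medians were 0.62 and 1.03, with camera adjusted p = 0.0695 (0.0123 with the replicate block) and 0.00309. With an estimated correlation adjusted p = 0.603 for the former with the block and 0.615 for the latter. G2 and M phase genes held 15 higher and 6 lower of 48 in linear (median 0.44, camera adjusted p = 0.543) and 29 higher and 4 lower in optimized polysomes (median 0.97, camera adjusted p = 0.0276, and adjusted p = 0.683 with an estimated correlation). HMGB2 (2.45) was higher and MYBL2 (-2.61) and BIRC5 (-1.95) lower in the latter. The secretory list held 26 higher and 5 lower of 74 in linear (median 0.38, camera adjusted p = 0.187) and 37 higher and 7 lower in optimized polysomes (median 0.56, camera adjusted p = 0.0192, and adjusted p = 0.615 with an estimated correlation). Among the higher were EPCAM (1.78 and 2.12) and CD9 (1.15 and 1.42). Long coding region mRNAs held 19 higher and 2 lower of 67 in linear (median 0.44, camera adjusted p = 0.187) and 32 higher and 2 lower in optimized polysomes (median 0.76, camera adjusted p = 0.0203, and adjusted p = 0.683 with an estimated correlation). In the blocked fit, 25 G1/S genes were higher and 5 lower, and 23 and 7 G2 and M phase genes, in linear polysomes. Secretory genes held 35 and 10 in linear and 39 and 13 in optimized polysomes, and long coding region mRNAs 36 and 4 in the latter. Less the median of all entries, the list medians were 0.36 and 0.73 for G1/S genes, 0.18 and 0.67 for G2 and M phase genes, 0.11 and 0.26 for secretory genes and 0.17 and 0.46 for long coding regions.

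The remaining lists did not pass by camera, and several held members that moved strongly in both directions. Other TOP mRNAs held 8 higher and 7 lower of 22 in linear (adjusted p = 0.540) and 9 and 8 in optimized polysomes (0.938). HNRNPA1 (1.13 and 1.89) and NPM1 (1.28 and 1.88) were higher and the elongation factors EEF1G (-2.20 and -2.03) and EEF2 (-1.63 and -1.41) lower. Of 11 mRNAs with inhibitory upstream reading frames, 2 were higher and 3 lower in linear (0.141) and 3 and 4 in optimized polysomes (0.0761), with C19orf48 (-3.10 and -3.84), ATF4 and UCP2 (-1.41 and -2.08) lower and IFRD1 (1.58 and 1.77) higher. The p53 targets held 19 higher and 15 lower of 80 (0.845) and 22 and 20 (0.777), with NINJ1 (-3.00 and -3.61) and TRAF4 (-2.76 and -3.30) lower and FUCA1 (1.86 and 2.19) higher. ATF4 targets held 7 and 6 of 33 (0.977), then 14 and 8 (0.702). Immediate early genes held 5 and 2 of 30 (0.982), then 6 and 4 (0.928), with JUND (-1.82 and -2.56) lower and MCL1 (1.42 and 1.96) higher. Cholesterol synthesis genes held 7 and 2 of 22 (0.845), then 11 and 3 (0.387), and interferon response genes 3 and 3 of 32 (0.982), then 12 and 7 (0.878). Glycolysis genes held 9 higher and 3 lower of 30 (0.543), then 16 and 0 (0.0696), with LDHA (1.75 and 2.30) higher. Epithelial markers held 1 higher and 2 lower of 8 (0.982), then 3 and 1 (0.489). MCF-7 markers held 2 and 0 of 7 (0.543), then 3 and 0 (0.489), fibroblast markers 1 and 0 of 7 (0.919), then 2 and 0 (0.702). Leukocyte markers held 1 and 1 of 7 (0.554), then 1 and 4 (0.326). TAF1D, the single tested transcript of the snoRNA host list, was higher in linear (1.10, adjusted p = 0.0129) and optimized polysomes (1.40, adjusted p = 0.00148) by edgeR's quasi-likelihood test. In linear polysomes the sign of the median changed with RLE or upper quartile scaling for p53 targets, other TOP mRNAs, upstream reading frame mRNAs, immediate early, cholesterol synthesis, interferon response and fibroblast genes, and in optimized polysomes for immediate early genes and epithelial markers. The median, mean and camera direction differed in sign for p53 targets and other TOP mRNAs in both gradients, and in linear polysomes also for ATF4 targets, upstream reading frame mRNAs, interferon response genes and epithelial markers. With the replicate block, linear polysomes held 23 higher and 24 lower p53 targets, 13 and 8 ATF4 targets, 7 and 5 immediate early genes, 9 and 5 cholesterol synthesis genes and 6 and 4 interferon response genes. Epithelial markers then held 3 and 5, fibroblast markers 2 and 0, and leukocyte markers 1 and 3. In optimized polysomes, cholesterol synthesis genes held 12 and 6 and glycolysis genes 16 and 1.

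**Figure D4:**
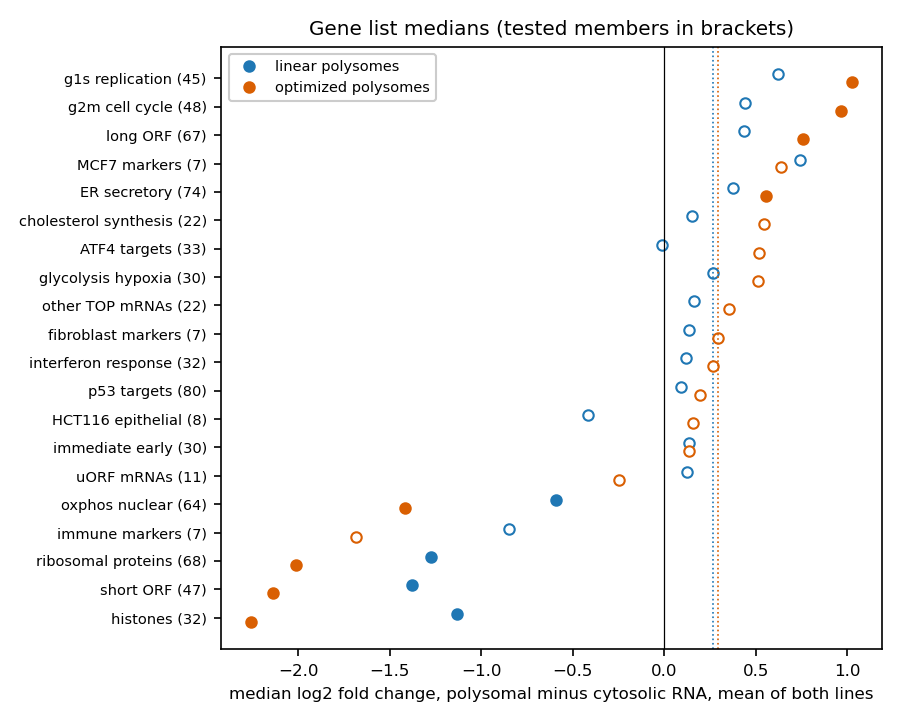
The horizontal axis gives the median log2 fold change of each gene list between polysomal and cytosolic RNA (TMM scaling), blue for linear and orange for optimized polysomes. Points are filled where camera's adjusted p with the preset correlation was under 0.05 and open otherwise. Dotted lines mark the median of all tested entries (0.27 and 0.30). The label uORF stands for upstream reading frame mRNAs. Ribosomal proteins lay at -1.28 and -2.01.

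The polysomal effects of both gradients were close across genes, with r = 0.939, rho = 0.933 and covariance 1.66, and 3001 entries were higher and 1829 lower in both, with none in opposite directions, where independent lists would share 1155 and 463. Both effects used the same cytosolic libraries, and unchanged groups simulated against those gave r = 0.528 (0.501 to 0.541 over 20 simulations) and a covariance of 0.109, against the 1.66 observed, although the simulations left out the lysates that both gradients share. With the cytosolic libraries split between the gradients, r was 0.731 and 0.738 and the covariance 1.58 and 1.56. FTL, GPX4 and RPLP0 were among the entries lower in both, and PICALM, BBX and GDAP1 among those higher in both.

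The last comparison asked whether p53 status changed how much of each mRNA was on polysomes relative to its cytosolic level. By edgeR's quasi-likelihood test of that interaction, 0 entries passed in linear (254 at an unadjusted p under 0.05, smallest adjusted p = 0.0519) and 0 in optimized polysomes (267, and 0.152). DESeq2 called 1 and 2, limma-voom 0 and 0, and upper quartile scaling 1 and 0. The count in linear polysomes was 1 without replicate 3 of the p53+/+ linear or of the p53-/- cytosolic libraries. Analysis of partial variance, in which the cytosolic level of the same lysate is a covariate, called 11 and 14 entries. Of these, chosen after the values were seen, ETV7 had 3.65 and 3.50 (adjusted p = 0.0459 and 0.0214 by limma with Benjamini-Hochberg adjustment). ZBED2 had -5.52 in optimized polysomes (adjusted p = 0.0252, same test). The interaction test gave ETV7 0.15 (linear) and 1.96 (optimized) and ZBED2 0.12 (each adjusted p = 1.00). Of the lists, oxidative phosphorylation genes, short coding region mRNAs and histones passed by camera in linear polysomes and oxidative phosphorylation and short coding region mRNAs in optimized polysomes, and none did with an estimated correlation. Across genes the effects of both gradients had r = 0.776, rho = 0.727 and covariance 0.740. Simulations with shared cytosolic libraries but without shared lysates gave r = 0.531 (0.497 to 0.555) and covariance 0.443. The excess over these is not free of lysate sharing. With separate cytosolic libraries for each gradient, almost no agreement was left, with r at 0.0163 and 0.0249 and covariance 0.0301 and 0.0455.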

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

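Among the tests in this part, those of GC content and of coding length as the whole cause, that of GC content between the gradients, those of abundant transcripts of other cells, of a single linear library with the replicate block, and of labels by genes called in the other kinds of RNA, and the settings with thinned counts, were chosen after the results were seen.

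Most genes that separated the lines lay outside the p53 target list, since 3.03% of the 66 genes called in all 3 kinds of RNA belonged to it, a share that restates the pattern and so decides nothing about that list as its source. Admixture had support from the fibroblast markers, which passed by camera in cytosolic RNA and optimized polysomes (adjusted p = 0.0354 and 0.0488) and with the replicate block in all 3 kinds of RNA (0.0146, 0.0134 and 0.00954), though not with the block and an estimated correlation (0.211, 0.149 and 0.164), and from the MCF-7 marker CA12, higher in cytosolic RNA of p53+/+ cells (3.87) while its list did not pass (0.886). The most abundant transcripts of such cells argue against it, since they summed to at most 0.0476 CPM for fibroblasts, 0.469 for MCF-7 and 0.966 for leukocytes, while the marker ACTA2 alone averaged 13.3 CPM in cytosolic RNA of p53+/+ cells. A mislabelled library is also argued against, since 0 of 24 libraries lay nearer to the other line's mean profile over genes called in the other kinds of RNA, and the smallest ratio of distances was 3.25. What may remain is loss of p53 acting on genes outside the list or separate histories of the lines, which are untested because the design holds a single line of each status.

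Optimized and linear polysomes differed in 355 entries, or 2688 with the replicate block. Without the linear library that is replicate 3 of p53+/+ cells, 0 of 355 calls were left, which decides nothing about it because leaving out any of 5 other libraries also left 0, whereas with the block 1903 entries were called without it, which argues against it there. Coding length and GC content may contribute, since Spearman's rho with the difference was 0.398 in both lines for length, and -0.359 in p53+/+ and -0.474 in p53-/- cells for GC content. Either as the whole cause is argued against, because 1271 (54.5%) of 2333 annotated calls were kept in the same direction after a length correction and 1517 (65.0%) after a GC correction, with the median size of those calls going from 0.73 to 0.54 and to 0.57. That the optimized fraction lay further from cytosolic RNA than the linear one stays open, as the difference in a line correlated with the polysomal effect in the other line at 0.490 and 0.491, as does an untested difference in ribosomes per mRNA.

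Polysomal and cytosolic libraries differed in many genes. Depth is argued against, since 5013 entries were called in linear and 6677 in optimized polysomes with thinned counts, against 5167 and 6859. GC content may contribute, with rho at -0.594 and -0.623, but as the whole cause it is argued against, because 2917 of 5884 annotated calls (49.6%) in linear and 4072 of 6998 (58.2%) in optimized polysomes were kept in the same direction after a GC correction. That correction took the median size of these changes from 1.15 to 0.55 and from 1.46 to 0.73. With it, 4232 annotated entries were called in linear and 5841 in optimized polysomes, so some calls were new or had changed direction. Coding length had rho at 0.218 and 0.323, with 4552 and 5451 calls kept after its correction, and a partial role of GC content, whether in amplification or in translation itself, stays open.

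Other splits of the libraries were counted for each comparison. For p53 status in cytosolic RNA the real split gave 177 calls, and 2 of 35 splits gave as many, so chance was not excluded by this count. The highest other, 533, put replicates 1 and 4 against 2 and 3 without parting any pair, whereas the 7 others that part all 4 pairs gave at most 3, and the block gave 830. In linear polysomes the real split gave 110 and the highest other 0, and 1 of 35 was as large. That share ignores the pairs and so does not by itself exclude chance. The splits that part all 4 pairs number 8, the real one included, too few for a share under 0.05, here and for the other comparisons of the lines. In optimized polysomes the real split gave 109, and 2 of 35 were as large, so chance was not excluded. The highest other, 833, put replicates 1 and 2 against 3 and 4, the 7 others that part as many pairs gave 0, and the block gave 349. These high counts point to a structure of the samples by replicate number.

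For optimized against linear polysomes the real split gave 355 and 4 of 100 drawn splits were as large. That share ignores the pairs made by shared lysates and so does not exclude chance. The highest other gave 2748 while parting 2 of 8 pairs, again a structure of the samples. The 7 others drawn that part all pairs gave 0, again too few for a share under 0.05. Within p53+/+ cells the real value was 0, all 35 of 35 splits were as large and the highest other was 0. Within p53-/- cells these were 0, 35 of 35 and 1366, the last from replicates 1 and 2 against 3 and 4, and the block gave 483. For linear polysomes against cytosolic RNA the real split gave 5167 and 1 of 100 was as large, with 3752 as the highest other and 3199 as the highest of the 7 others that part all pairs. For optimized polysomes these were 6859, 1 of 100, 5658 and 5454. Both shares ignore the pairs too, so they do not by themselves exclude chance. For the interactions of p53 status with polysomal against cytosolic RNA the real values were 0 and 0, with 35 of 35 splits as large and highest others of 1 in linear and 2 in optimized polysomes. For the p53 effect between gradients the real value was 0, with 35 of 35 splits as large and 0 as the highest other.

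A library apart from its group was the cytosolic replicate 1 of p53-/- cells, in which the 20 most abundant entries took 11.8% of the counts against 15.7% to 15.9% in the other 3 libraries. The gap was 0.958 of the group's range. A gap past the limit used arises in about 1 in 20 groups of 4 by chance, and 48 such groups were examined. Several lists differed between lines or gradients by a camera test of the difference itself. In linear polysomes relative to cytosolic RNA, oxidative phosphorylation genes (adjusted p = 3.40e-05, median 0.45), histones (adjusted p = 0.0129, median 0.53) and short coding region mRNAs (adjusted p = 0.000371, median 0.44, above 0 in 47 of 47) lay higher in p53+/+ cells. In optimized polysomes, oxidative phosphorylation genes (median 0.33) and short coding region mRNAs (median 0.37) did so with adjusted p = 0.0444 each. The p53 effect was lower with the optimized gradient for ribosomal proteins (adjusted p = 0.000582, median -0.12), oxidative phosphorylation genes (adjusted p = 0.0376, median -0.08), interferon response genes (adjusted p = 0.0369, median -0.12) and long coding region mRNAs (adjusted p = 0.0133, median -0.16). With an estimated correlation, adjusted p was 0.968 for the lists in linear and 0.935 for those in optimized polysomes, and 0.936 for the last group except for interferon response genes (0.802).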

How the results depend on the processing

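The settings with thinned counts, GC or coding length corrections, merged entries in lists, and the block with an estimated correlation were chosen after the results were seen. Of the values of named genes under alternatives, 3291 kept their direction and side of the threshold, 455 lost the call and 0 reversed. Of the counts and summary values, 290 stayed within 1.5 times or 1 SD and 114 moved. The cause was not tested where none is given. The replicate block ended 0 and added 87 calls of genes named by rule, ended 0 and added 8 calls of lists, and changed no other call of these. For genes, lists and member counts given in the report, its value stands there where it changed the call or moved the count by over 1.5 times.

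With RLE scaling 12 entries (7 higher, 5 lower) differed between optimized and linear polysomes, against 355 (78 higher, 277 lower), and with upper quartile scaling the interaction in linear polysomes gave 1. Without a filter the gradients gave 89 and with the stricter filter, which tests fewer entries, 584. The stricter filter also gave r = 0.862 between the p53 effects, a share of 48.5% within 1 log2 unit and a coefficient of variation of 0.404 in linear p53+/+ libraries. Restricted to genes past the threshold with either gradient, r was 0.918. With a bound of 0.5 in place of 1, the share was 1.92%, a narrower bound by construction.

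With the replicate block, p53 status gave 830 entries in cytosolic RNA, 295 in linear and 349 in optimized polysomes, and the gradients gave 2688, with 10 in p53+/+ and 483 in p53-/- cells. These included all 177, 110, 109 and 355 entries called without it. The lysate block gave 2534 between gradients, 368 in p53-/- cells and a share of 52.4%. With the block on annotated entries, the gradients gave 2242 after a GC and 1682 after a length correction. With only the groups compared, cytosolic RNA gave 56 and the gradients 235, from fewer libraries.

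DESeq2 gave 388, 222 and 223 for p53 status in cytosolic RNA, linear and optimized polysomes, 1260 between gradients and 11 within p53-/- cells. It gave 1 and 2 for the interactions in linear and optimized polysomes and 1 for the p53 effect by gradient. limma-voom gave 101, 168 and 182 for p53 status and 585 between gradients. An absolute change of at least 1 log2 unit left 83 between gradients. Analysis of partial variance gave 11 and 14 for the interactions.

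Of the lists past the threshold by camera, 0 of 11 in cytosolic RNA, 2 of 8 in linear and 3 of 11 in optimized polysomes stayed for p53 status with an estimated correlation. Then 4, 3 and 4 passed by fry, and 0, 4 and 4 with the block and an estimated correlation. Between gradients these were 0 of 12, 5 and 0, and 0, 0 and 0 in each line. For polysomal against cytosolic RNA they were 0, 11 and 0 in linear and 0, 17 and 0 in optimized polysomes. For the interactions and for the p53 effect by gradient they were 0, 0 and 0.

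Leaving out a library gave 118 to 201 entries for p53 status in cytosolic RNA, 67 to 85 in linear and 63 to 102 in optimized polysomes, 0 to 545 between gradients, 4481 to 5463 for linear and 6516 to 6974 for optimized polysomes against cytosolic RNA. It gave 0 to 1 for the interaction in linear polysomes and 0 for the interaction in optimized ones, the p53 effect by gradient and the gradients in each line. Leaving out a whole replicate number gave 55 to 117, 42 to 74 and 40 to 83 for p53 status, 0 between gradients, 3588 to 5015 and 5597 to 6541 for polysomal against cytosolic RNA, and 0 for the interactions. The correlation of the p53 effects was then 0.611 to 0.640, that of the interactions 0.757 to 0.785, and the share within 1 log2 unit 26.9% to 38.5%. The coefficient of variation was 0.398 to 0.501 and 0.371 to 0.496 in linear and 0.367 to 0.518 and 0.413 to 0.524 in optimized libraries of p53+/+ and p53-/- cells.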

Other observations

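The selenoprotein test in this part was chosen after the genes most depleted from polysomes had been seen. Selenoproteins carry selenocysteine, which is read from a stop codon, and several of their mRNAs were among the lowest in polysomal relative to cytosolic RNA. With the replicate block, GPX4 lay at -5.50 in linear and -5.94 in optimized polysomes, SEPW1 at -5.26 and -5.61, GPX1 at -4.12 and -4.51, SELM at -3.53 and -4.37, and MSRB1 at -2.77 and -3.60. TXNRD1 (1.40 and 1.86), VIMP (1.27 and 1.14) and SELK (1.13 and 0.83) lay higher. Of 15 tested selenoproteins, 7 were lower and 5 higher in linear and 8 lower and 3 higher in optimized polysomes.

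The hypothesis that selenoprotein mRNAs may be depleted beyond their GC content and coding length was tested against 10000 random lists drawn from genes matched on both and on expression. The selenoprotein medians, -0.52 and -0.99, lay at percentiles 47.0 and 41.4 of those lists, whose medians were -0.50 and -0.86. As members were called both ways, their median decides nothing, and the hypothesis stays open.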
